A study of Mus musculus with 10 samples.

How the data were processed

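The deposited files hold, for each of 10 mice, the scanner output of 1 single-colour Agilent mouse array (Cy3), with 45018 spots, of which 43379 were not controls and represent 41174 probes. Each intensity had been extracted by the authors with Agilent Feature Extraction 10.5.1.1, per the file headers, which also record spatial detrending and multiplicative detrending behind the processed signal. A flag per spot, made by the same software per the file headers, says whether the spot was well above background. The deposited value table holds log2 values of the same arrays, as set against the scanner values: each of its 10 columns correlated best with the log2 mean signal of its own array (0.967 to 0.996), all columns share the maximum of 18.9, and their medians lie between 6.96 and 6.97. Deviations from the probe mean in this table correlated at 0.985 to 0.993 with those of normexp and quantile-normalised values. The offset or background method the authors used for it is not given in the sources used here.

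Groups, ages, sexes and mouse numbers were taken from the labels. Genotype is +/L (5 mice) or +/+ (5 mice). Slides were numbered 1 to 3. The slide in the file headers grouped the arrays as the file names do, and the description label gave another slide for 2 arrays (mice 866 and 17); by the headers, the slides held 2, 2 and 1 +/L arrays and 2, 1 and 2 +/+ arrays, so that genotype could be compared within each. By the description labels, slide 38 held 0 +/L and 3 +/+ arrays. A block on those labels therefore takes these 3 +/+ arrays out of the genotype comparison. The replicates carry separate mouse numbers and were treated as separate animals.

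Values are log2 of the processed signal minus the array's 75th percentile of it over non-control spots. Control spots and population or non-uniformity outliers were left out, 0 non-control spots were saturated, and spots of a probe were averaged. Probes were kept when well above background on at least 3 of 10 arrays (26410 probes), and 73 probes with an outlier flag on an array were left out. Per gene, the probe with the highest mean stood for the gene. Probe names were brought up to date through a table of RefSeq genes: 25097 probes matched by accession, 6333 by symbol and 1640 by synonym, and 8104 kept the name in the files. This left 17775 genes and unnamed transcripts, 14798 of them with a current symbol. The transcript records that the files list for the named probes were also looked up in that table. Coordinates are those the files give for the probes (mm9); exon, intron and UTR annotation was not used here. A filter on dim probes sets which genes can be tested, and scaling sets the balance of higher and lower calls, so both were varied.

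Genotypes were compared with limma 3.58.1 (lmFit and eBayes, trend and robust off) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no covariate. Of 38 gene lists fixed before the data were examined, 3 served as quality lists; 35 were tested, each needing 4 kept genes. A tumour's list score is the mean over members of the log2 value minus the gene's mean over the 10 tumours, and scores were compared with an exact two-sided permutation test over all splits, adjusted over the 35 lists. Camera, with a preset correlation of 0.01 and with an estimated one, and fry were alternatives. Named genes were chosen by a rule fixed before the data were examined: the C/EBP family; per direction the 10 largest changes among genes past the threshold with non-overlapping groups, filled up to 8 genes of lowest unadjusted p with an absolute log2 difference of at least 1 where fewer than 8 passed; the 3 members of lowest p in each list that passed, or else in the 5 lists of lowest p; Xist and Y-linked genes; and the lineage genes Cd79a, Cd3e and Cd8a, with one more that is not reported here. Genes without a symbol, clone-type names and rearranging receptor segments were left out of the second part. Other genes named were chosen after their values were seen: Serpina1d, Serpina3m, H60a, Alb, Apoa1, Ttr, S100a9, Cxcr2, Ccl3, Ccl4, Arg1, Saa3, Acta2, Tagln and Cnn1, the last 12 as members of fixed lists.

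Alternatives changed the background correction (normexp, offset 50, only together with quantile normalization), normalization, filter, probe rule, test, covariates (age, sex, a B-minus-T score), slide block and the set of arrays, otherwise one at a time; fits with a covariate or block used limma on the list scores. Chosen after seeing the data were the adipocyte score as a covariate, limma on list scores without a block, and leaving out the 2 mice whose sex-linked transcripts disagree with the labels. The procedure was tested on simulated data with the real means and spreads of 17775 genes, drawn as independent, of which 200 were changed, in 10 runs: it recovered 15.5% of genes changed by 1, 57.8% of those changed by 2 and 76.1% of those changed by 3 on the log2 scale for this comparison of 5 with 5 arrays, with 4.99% false calls. In simulated scores of 35 lists, a shift of 3 SD in 5 lists was called in 6% of them by the exact test.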

Results

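Messenger RNA was profiled in spontaneous lymphomas of 10 mice. C/EBPβ is a transcription factor made as several isoforms from one mRNA, and LIP is its shortest isoform, which starts at a downstream start codon and lacks most of the activating part of the protein. The tumours came from 5 mice heterozygous for an allele that gives the LIP isoform (+/L) and from 5 wild-type mice (+/+), with 1 single-colour 60-base oligonucleotide array per mouse, so each n counts tumours of separate animals. The mice with +/L tumours were killed at 18 ± 4.06 months (SD, n = 5) and the +/+ mice at 24.9 ± 3.47 months (SD, n = 5), a difference of -6.9 months (exact two-sided permutation test, p = 0.032). Without +/+ mouse 40, 11 or 101 the difference was -6.625, -5.875 or -6.5 months (exact permutation p = 0.056 each). Between 48.0% and 66.7% of the non-control spots of an array were well above background. The share was 59.9% ± 6.89 in +/L and 59.3% ± 4.91 in +/+ tumours (exact permutation p = 0.86). The 75th percentile of the processed signal, to which every value below is relative, was 434 ± 129 in +/L and 288 ± 61.1 in +/+ tumours (SD, n = 5 each, exact permutation p = 0.032). The number of arrays limits the precision of all comparisons.

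The level of Cebpb, the altered gene, was examined first. Its brighter probe (A_52_P63553, chromosome 2, 167515847 to 167515905 in mm9, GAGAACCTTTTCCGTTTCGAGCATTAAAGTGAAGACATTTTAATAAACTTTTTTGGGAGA) read 2.69 ± 0.72 in +/L and 3.42 ± 0.81 in +/+ tumours on the log2 scale (SD, n = 5 each). The difference of -0.74 was within the spread between tumours (exact two-sided permutation p = 0.17, limma adjusted p = 0.66). The other probe (A_52_P605846, 167515309 to 167515368) differed by -0.53 (exact permutation p = 0.25). With the slide as a block the brighter probe differed by -0.48 (limma adjusted p = 0.78), and within the 3 slides by -0.15, -0.94 and -0.51. The probes start at bases 894 and 1424 of their transcript records, and their level was not taken as a check of the genotype labels, since LIP is translated from the same mRNA. Of the other family members, Cebpa differed by -0.45 (limma adjusted p = 0.76), Cebpd by 0.12 (adjusted p = 0.95) and Ddit3, the stress-induced member also called CHOP, by 0.11 (adjusted p = 0.92). Cebpg differed by 0.60 (adjusted p = 0.56), but its 2 other probes read 0.03 and -0.09. None of the 5 family genes passed when adjusted over the list alone, and the sign of the Cebpd and Ddit3 differences turned in some settings.

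The sex in the labels was compared with Xist, the RNA expressed from the inactive X chromosome, and with Y-linked genes. All 7 female-labelled arrays had Xist well above background, from 1.83 to 4.18, and 0 of them had Ddx3y, Eif2s3y or Kdm5d well above background. Of the 3 male-labelled arrays, only that of +/+ mouse 101 had the Y-linked genes, with Ddx3y (chromosome Y, 598215 to 598274 in mm9) at 0.08, Eif2s3y at 1.18 and Kdm5d at -2.06, and its Xist (chromosome X, 100658920 to 100658979) was not well above background. The arrays of +/L mouse 20 and +/+ mouse 11, labelled male, had Xist at 2.17 and 3.44 and none of these 3 Y-linked genes well above background. A further Y-linked gene, Uty, went another way: its probe was well above background only on the array of +/L mouse 20 (-3.33), and not on that of +/+ mouse 101 (-6.28), so it was left out of this check. By the other genes, 2 of 10 arrays did not match the sex in their labels. A fit with the labelled sex as the only term called 0 genes at adjusted p under 0.05 in limma. It had 2477 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.098. The filter on dim probes had removed the Y-linked genes from this fit, and 2 of the 3 male labels did not match the arrays. The count of 0 therefore tells nothing about sex differences or about the sensitivity of the procedure.

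**Figure D1:**
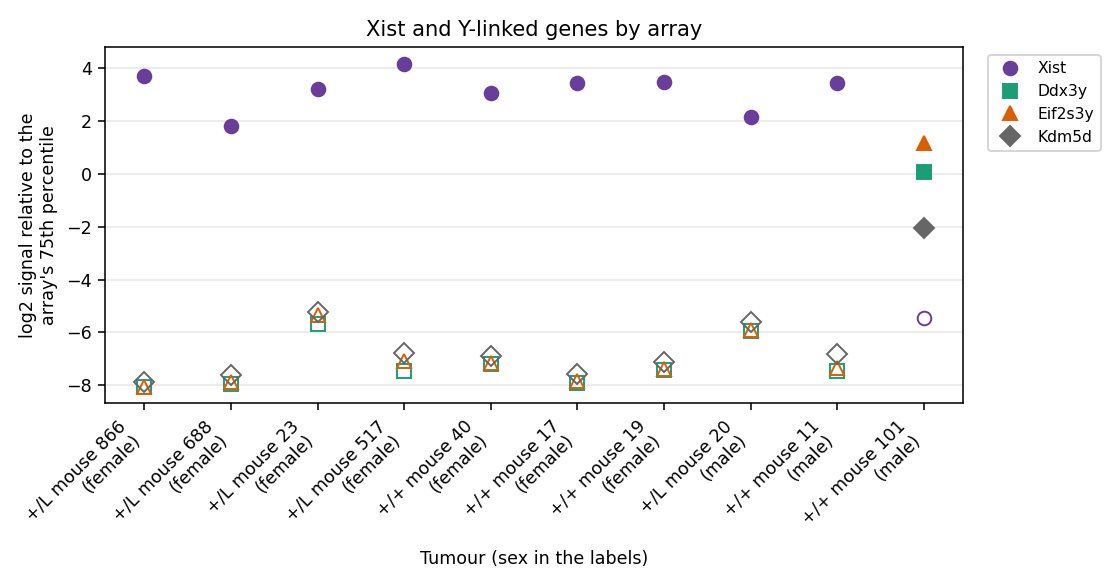
Log2 signal relative to the array's 75th percentile (vertical axis) of Xist and 3 Y-linked genes in each of the 10 tumours (horizontal axis, with the sex in the labels); filled points are well above background and open points are not. The only array with signal of these 3 genes is that of +/+ mouse 101, and Xist is filled on the other 9 arrays.

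The tumours carried B-cell and T-cell transcripts side by side, and the 3 lineage genes named here did not pass between the genotypes. Cd79a, part of the B-cell receptor, read 0.71 ± 1.26 in +/L and 1.01 ± 0.35 in +/+ tumours (SD, n = 5 each). Cd3e, part of the T-cell receptor complex, read -0.32 ± 0.63 and 0.46 ± 0.97, and Cd8a, the co-receptor of cytotoxic T cells, read 2.80 ± 1.14 and 2.16 ± 1.32. The limma adjusted p-values of these 3 genes lay between 0.67 and 0.90. In the youngest mouse, +/L mouse 866 at 11 months, Cd79a was at -1.52 against 1.13 to 1.55 in the other +/L tumours, and the score of 20 B-cell markers was -1.54. The tumour of +/L mouse 20 had the highest plasma cell score, 2.24, with a T-cell marker score of -1.62. Over the groups, the B-cell marker score differed by -0.27 (exact permutation p = 0.64), the T-cell marker score by -0.17 (p = 0.78), the germinal centre score by -0.27 (p = 0.70) and the plasma cell score by 0.06 (p = 0.95), each with an adjusted p of 1. The sign of the B-cell difference rested on +/L mouse 866, with the other +/L tumours at -0.47 to 0.84. That of the T-cell difference rested on +/L mouse 20, with the other +/L tumours at -0.50 to 0.87. Within the 3 slides the B-cell marker score differed by -0.20, 0.33 and -1.69 and the T-cell marker score by -0.05, 0.78 and -0.46. The signs for Cd79a and Cd8a depended on +/L mouse 866 or on age: without that mouse Cd79a differed by 0.25, and with age as a covariate Cd8a differed by -0.03.

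Genes that differ between +/L and +/+ lymphomas were sought in the main comparison, which the series was designed for. No gene passed. The genes with the lowest p, among those with a symbol and an absolute log2 difference of at least 1, are given as values. On the side of higher values in +/L, Tph1, which makes serotonin outside the nervous system (chromosome 7, 53902606 to 53902665 in mm9) and was well above background on 5 of 5 +/L and 3 of 5 +/+ arrays, read -2.10 ± 0.67 in +/L and -4.76 ± 0.43 in +/+ tumours, a log2 difference of 2.66 ± 0.34 (SE) with a limma adjusted p of 0.082. With the slide as a block it differed by 2.74 (adjusted p = 0.20), and within the slides by 3.02, 2.19 and 2.86. Aldh1a2, a retinoic acid synthesis enzyme, differed by 2.01 ± 0.38 (adjusted p = 0.39), Serpina3c, well above background on 4 of 5 +/L and only 1 of 5 +/+ arrays, by 3.11 ± 0.50 (adjusted p = 0.22), Tmie by 1.92 (adjusted p = 0.47) and Ramac, a cofactor of mRNA cap methylation, by 1.52 (adjusted p = 0.47). A further 3, Npr3, a natriuretic peptide clearance receptor, Prss55, a protease, and Fst, which binds activin, were not well above background on any +/+ array. On the +/L arrays they were well above background on 4, 3 and 4 of 5. By the group means, the bound on +/L over +/+ was 2.31-fold, 1.38-fold and 1.40-fold (limma adjusted p = 0.18, 0.39 and 0.39). In these bounds, which also apply to Olfr154, AK043110 and Arg1, the mean of the brighter group was set against the dim group. Each array of the dim group stood at the higher of its own reading and its lowest well-measured signal. Arrays of the brighter group kept their own reading, also where it was not well above background, so the bounds are not strict minimum values. The bounds take no account of the spread between tumours and hold for the main processing only. Over the alternatives the log2 differences shrank to 0.24 for Npr3, 0.13 for Prss55, 0.15 for Fst and -0.10 for Olfr154.

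On the side of lower values in +/L were Serpina1b and Serpina1c, which encode protease inhibitors called α1-antitrypsin proteins. These 2 genes read -1.19 ± 0.79 and -1.35 ± 0.73 in +/L against 1.62 ± 0.66 and 1.28 ± 0.62 in +/+ tumours (SD, n = 5 each). Their log2 differences were -2.81 ± 0.43 and -2.63 ± 0.40 (SE), each with a limma adjusted p of 0.18. With the slide as a block Serpina1b differed by -2.90 (adjusted p = 0.32), and within the slides by -2.87, -1.64 and -4.22. The Serpina1c probe is listed in the files for transcripts of 4 genes, Serpina1b to Serpina1e, so these values do not count as independent genes. Vim, the intermediate filament vimentin, differed by -1.03 ± 0.20 (adjusted p = 0.41), Actg2, a smooth muscle actin, by -1.61 ± 0.33 (adjusted p = 0.47), Synpo, an actin-binding protein, by -1.99 ± 0.38 (adjusted p = 0.40) and Nosip, which binds nitric oxide synthase, by -1.36 ± 0.23 (adjusted p = 0.31). The olfactory receptor gene Olfr469, well above background on 3 of 5 +/L arrays, differed by -1.04 (adjusted p = 0.39). Olfr154, not well above background on any +/L array, was lower with a bound of 1.31-fold (adjusted p = 0.47), and its probe is also listed for Olfr1002. In all 16 of these genes, which were picked for their low p, the groups of 5 values did not overlap. With age as a covariate Synpo differed by -1.20. Single probes carry some of them: another Nosip probe differed by 0.04, another Synpo probe by -0.66 and 1 of 3 Ramac probes by -0.50.

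**Figure D2:**
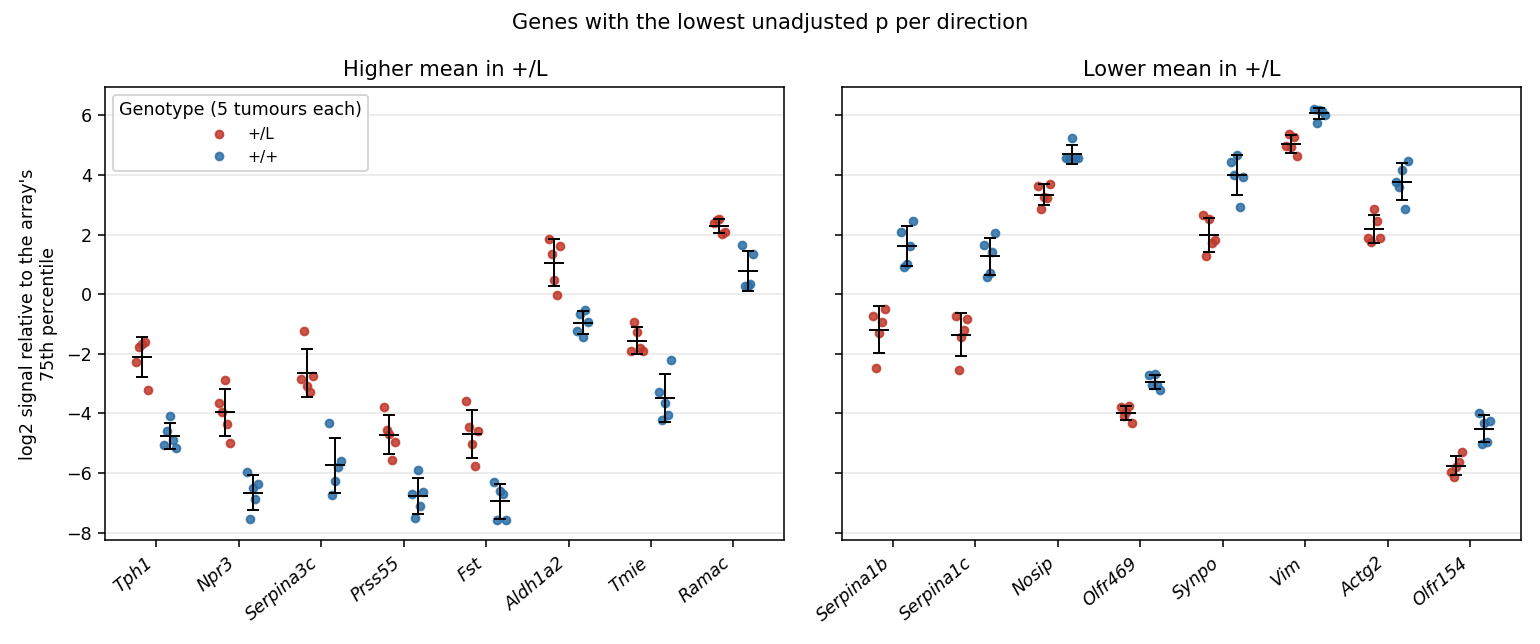
Log2 signal relative to the array's 75th percentile (vertical axis) of 8 genes in each direction (horizontal axis). They have the lowest unadjusted p among genes with a symbol and an absolute log2 difference of at least 1, without clone-type names. Points are tumours (+/L red, +/+ blue, 5 each), and bars are the mean and SD. Tph1 lies between -3.21 and -1.62 in +/L and between -5.17 and -4.10 in +/+ tumours; none of the 16 genes passed adjusted p 0.05.

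Of 17775 genes and unnamed transcripts tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.082. It was shared by Tph1 and the transcripts AK043110 and ENSMUST00000070897 (-3.03), the last 2 chosen after their values were seen. AK043110 was higher in +/L with a bound of 1.63-fold, and not well above background on any +/+ array. An unadjusted p under 0.05 was reached by 1525 genes, 558 higher and 967 lower in +/L, where chance gives about 889. When arrays were scaled to the median of well-measured probes the split was 711 higher and 726 lower. The 5 values of each group did not overlap in 320 genes, or 1.80%, against 0.79% by chance. This share was not set against other splits of the tumours, so chance is not excluded for it. With the slide of the headers as a block, 0 genes passed, and 1346 had an unadjusted p under 0.05. With the slide of the description labels 669 had, in a fit that loses 3 of the 5 +/+ arrays from the genotype comparison. Without +/L mouse 20 that count was 2314, without +/+ mouse 101 it was 913, and without mice 20 and 11 it was 2521, with 0 genes past adjusted p 0.05 each time. Without +/L mouse 517, 3 genes passed in limma: Tph1 (2.94, adjusted p = 0.012), ENSMUST00000070897 and H60a, the last 2 chosen after their values were seen. On normexp and quantile-normalised values the differences of dim genes were smaller, 0.86 for Tph1, 0.87 for Tmie, 0.69 for Serpina3c, 0.40 for Npr3 and -0.39 for Olfr469. The offset of 50 added there to every signal shrinks log2 differences of dim genes by itself, so this does not test their size. ENSMUST00000070897 passed on these values (limma adjusted p = 0.0195).

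Cell type and pathway differences were examined with gene lists, scored per tumour. Of 35 lists fixed in advance, 0 passed the exact permutation test after adjustment, and the smallest adjusted p was 0.91. The test can give no p below 0.0079, so that at least 6 lists would have to reach it before any could pass; limma on the same scores, with genotype as the only term, also called 0 lists (smallest adjusted p = 0.83). NF-κB targets and survival genes had the lowest p, with a score difference of -0.44 (exact permutation p = 0.071) and 14 of 16 members lower in +/L. In +/L mouse 20 the score was -1.02, against -0.19 to 0.19 in the other +/L tumours, and without it the difference was -0.24 (exact permutation p = 0.13). On normexp and quantile-normalised values of all 10 tumours it was -0.26. Among them Relb, an NF-κB subunit, differed by -0.70, Nfkbia, the NF-κB inhibitor, by -0.58 and Icam1, an adhesion receptor, by -0.66 (limma adjusted p = 0.57 each). Among the female-labelled mice Relb differed by -0.41 and Icam1 by -0.23, and with age as a covariate Nfkbia by -0.32. Glycolysis genes differed by -0.61 (exact permutation p = 0.15), with 17 of 18 members lower. The score was 0.98 and 1.07 in +/+ mice 11 and 101, which also had the highest mitosis scores, and -0.43 to -0.04 in the other +/+ tumours. The difference was -0.26 with age as a covariate and -0.08 among the female-labelled mice (exact permutation p = 0.89). The members included Slc2a1, the glucose transporter GLUT1, at -0.75 (limma adjusted p = 0.54), Gpi1 at -0.74 and Gapdh at -0.99 (adjusted p = 0.56 each). With age as a covariate these 3 were at -0.39, -0.38 and -0.44. The score of 14 housekeeping genes, a quality list that includes glycolytic transcripts, differed by -0.35 (exact permutation p = 0.10) and that of 16 immediate early and handling stress genes by -0.37 (exact permutation p = 0.056).

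Adipocyte, mast cell and neutrophil lists had the largest score differences of the 35, and none of them passed. Mast cell and basophil markers differed by 1.53 (exact permutation p = 0.095), with 7 of 8 members higher in +/L. The scores overlapped, from -1.25 to 2.44 in +/L and from -1.79 to 0.23 in +/+ tumours. Hdc, which makes histamine, differed by 1.75 and Gata2, a mast cell transcription factor, by 0.90 (limma adjusted p = 0.56 each), and Fcer1a, the IgE receptor chain, well above background on 3 of 5 +/L and 2 of 5 +/+ arrays, by 2.08 (adjusted p = 0.57). With age as a covariate Hdc differed by 0.95, Gata2 by 0.09 and Fcer1a by 2.54. Within the 3 slides Fcer1a differed by 3.87, -1.30 and 2.50. In +/L mice 688 and 517 Hdc was at -1.73 and 0.39, where the list score was 2.44 and -1.25. Adipocyte genes differed by 1.80 (exact permutation p = 0.14), with 8 of 10 members higher in +/L. Cfd, the serum protease adipsin, was at 5.03 ± 1.98 (SE), Cidec, a lipid droplet protein, at 4.22 ± 1.70 and Retn, the hormone resistin, at 3.44 ± 1.27 (limma adjusted p = 0.55 to 0.56). The 2 lower members were Pparg at -1.22 and Pnpla2 at -0.33, and Lpl and Lipe differed by 0.26 and 0.19. Of the 5 +/+ arrays, 4 had Cfd, 2 had Cidec and 1 had Retn well above background. With the slide of the file names and headers as a block Cfd, Cidec and Retn differed by 5.59, 4.64 and 3.62 (limma adjusted p = 0.62 each). With the slide of the description labels they differed by 2.58, 2.23 and 1.91, but that block takes 3 of the 5 +/+ tumours out of the genotype comparison. On normexp and quantile-normalised values, with the offset of 50, Cidec differed by 2.42, Retn by 1.23, Fcer1a by 0.41 and Gata2 by 0.38. The adipocyte score was 1.78 in +/+ mouse 40 and -1.66 in +/L mouse 517, against the direction of their groups. Lipid and adipogenic C/EBP targets, which share Retn, Cidec and Fabp4 with the adipocyte list, differed by 0.86 (exact permutation p = 0.17), with 7 members higher and 6 lower and a median member difference of 0.05. The difference was -0.20 with the adipocyte score as a covariate and 0.49 without +/L mouse 688 (exact permutation p = 0.40), whose score was 1.94. The adipocyte score is made in part of the shared genes, so as a covariate it takes out part of the difference by itself. The Fabp4 difference was 1.5 (limma adjusted p = 0.59). It was 0.94 with age as a covariate, 0.84 among the female-labelled mice and 0.70 with the slide of the description labels. With the adipocyte score as a covariate, of which Fabp4 is itself a member, the Fabp4 difference was 0.59. Neutrophil and granule genes differed by 1.47 (exact permutation p = 0.18), all 15 members higher in +/L, of which S100a9 was at 2.99 and Cxcr2, a chemokine receptor, at 2.11 (limma adjusted p = 0.57 and 0.56).

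Within the 3 slides, the mast cell score differed by 2.34, 1.06 and 1.65. With the slide given in the file names and headers as a block, it differed by 1.78 ± 0.34 (SE, limma on the scores, adjusted p = 0.015) and was the only list that passed; without the block the same fit gave an adjusted p of 0.83, with the slide of the description labels 0.92, and the adjusted p over all alternatives ran from 0.015 to 1. The difference was 0.54 with the adipocyte score as a covariate, 0.92 without mice 20 and 11, 1.01 with age as a covariate, 0.86 among the female-labelled mice and 0.78 on normexp and quantile-normalised values. The adipocyte score differed by 1.87, 1.64 and 2.63 within slides and by 2.02 with the block (adjusted p = 0.29). It differed by 0.77 with the slide of the description labels and 0.99 among the female-labelled mice. The neutrophil score differed by -0.50, 2.53 and 4.14, the NF-κB score by -0.80, 0.14 and -0.53, the lipid target score by 1.15, 0.50 and 1.12 and the glycolysis score by 0.01, -1.42 and -0.68 within slides. Camera with its preset correlation called 6 lists (glycolysis, neutrophil, NF-κB, mast cell, adipocyte and interferon-stimulated genes), and 0 of them held with an estimated one (adjusted p = 0.997 for each with an estimated correlation).

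Inflammatory mediators linked to C/EBPβ went both ways, with a mean score difference of 0.08 (exact permutation p = 0.88) and a median member difference of -0.24. The score was 1.42 in +/L mouse 866, against -0.69 to 0.13 in the other +/L tumours. Within the 3 slides it differed by -0.12, -0.27 and 1.33. The chemokine genes Ccl3 and Ccl4 differed by -1.99 and -1.69, and these 2 members passed when adjusted over the list alone, while 0 passed over all genes tested (limma adjusted p = 0.54 each). Arg1, arginase, was higher in +/L with a bound of 8.79-fold (limma adjusted p = 0.54). It was well above background on 3 of 5 +/L and on no +/+ arrays. Saa3, an acute-phase protein, was at 2.75. In the smooth muscle and pericyte list Actg2, Acta2 (-1.44) and Tagln (-1.12) passed when adjusted over the list alone, and Cnn1, well above background on 3 of 5 +/L and 1 of 5 +/+ arrays, was at 2.90; the list score difference was 0.00. These 2 lists were the ones fry found to change in either direction (adjusted p = 0.0072 and 0.0094), and fry called 0 lists on balance in one direction. In 9 of the 35 lists the score difference and the median member difference had opposite signs.

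**Figure D3:**
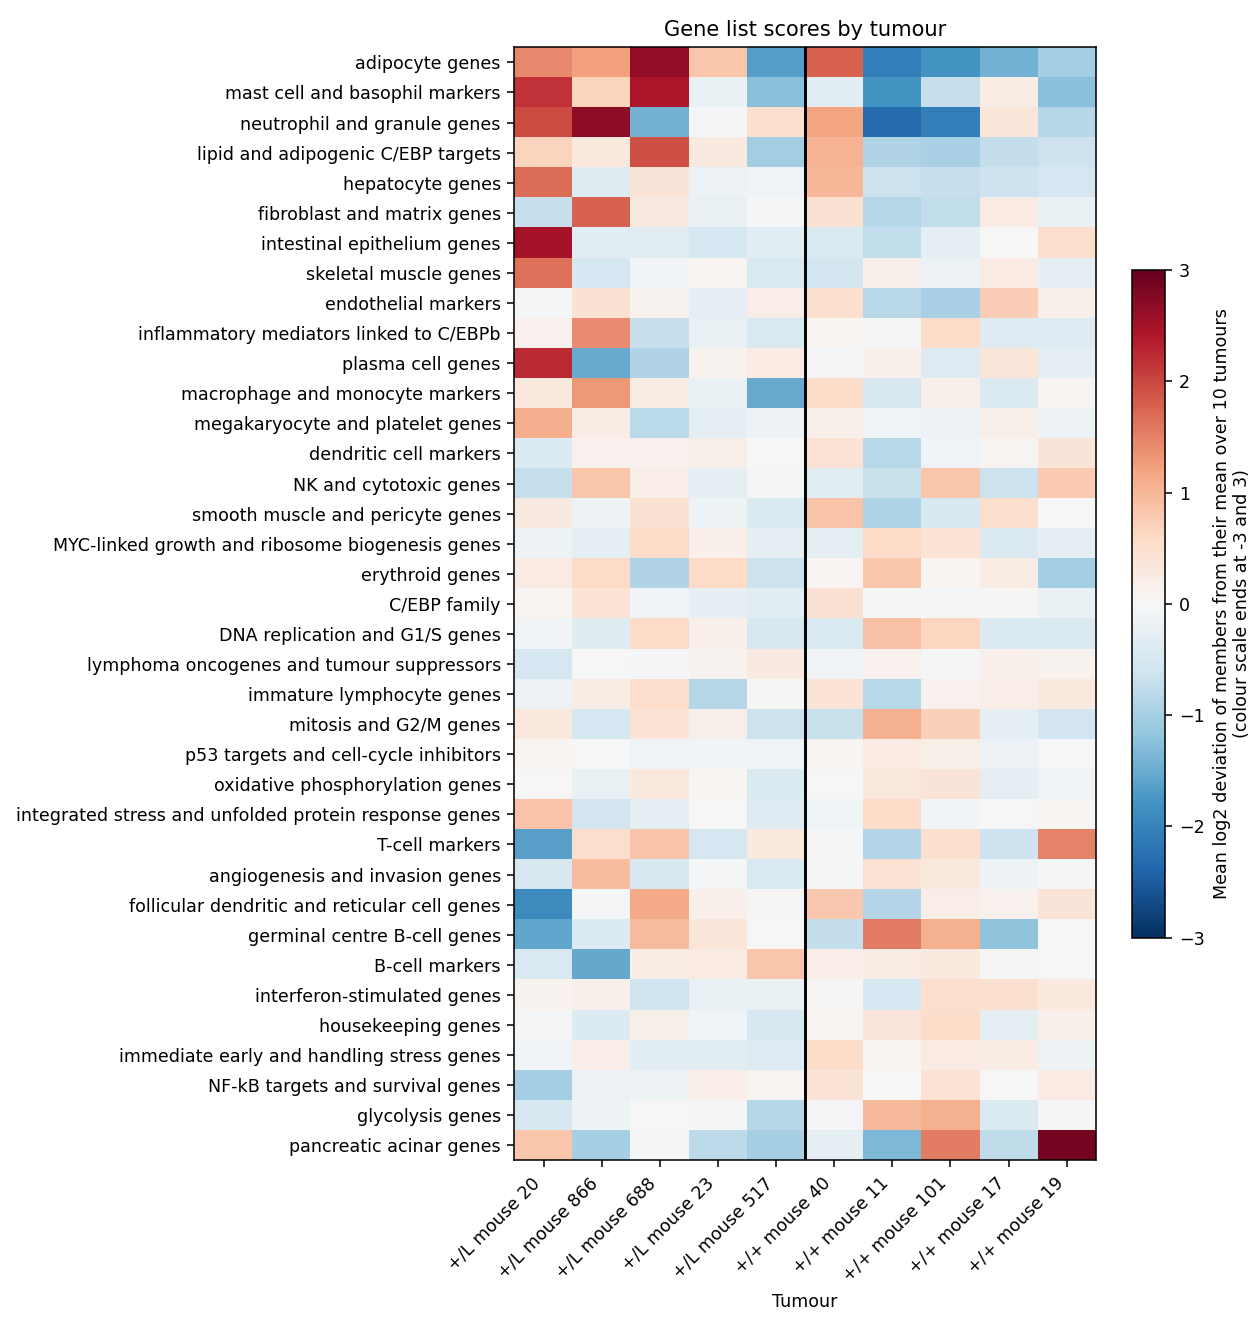
Gene list scores (colour, the mean log2 deviation of the members from their mean over 10 tumours, with colours saturating at -3 and 3) of 37 lists in rows and the 10 tumours in columns, +/L left of the line and +/+ right of it. Adipocyte scores run from -1.66 to 2.66 in +/L and from -2.05 to 1.78 in +/+ tumours, so the groups overlap.

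Whole profiles were compared to ask whether genotype orders the tumours. The median Pearson correlation across genes was 0.946 within genotypes (0.932 within +/L and 0.956 within +/+) and 0.941 between them (exact one-sided permutation over all splits, p = 0.20), where genes are not independent replicates. Over the 1000 most variable genes it was 0.679 within (0.589 within +/L and 0.728 within +/+) and 0.599 between (exact permutation p = 0.048), so that only +/+ tumours were more alike than tumours of different genotypes. The spread between tumours of a genotype was compared next: the median SD of a gene was 0.561 in +/L and 0.429 in +/+, and the median log2 ratio of variances was 0.76 (exact two-sided permutation p = 0.048). Without +/L mouse 20 that ratio was 0.21 (exact permutation p = 0.36), and without any 1 of +/L mice 866, 688 and 517 and +/+ mice 40 and 101 it was 0.69 to 0.87 (exact permutation p = 0.063 to 0.079). The array of +/L mouse 20 had a median correlation of 0.882 with the others, against 0.932 to 0.957 for the remaining 9.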

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

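The tests of sex labels, liver RNA and haplotypes, and those of fat and age on 5 genes, were chosen only after the result was seen; that of probe identity was set before. Of 164 groups of 5 values examined, 15 had a value far from the other 4, where chance gives about 8.2.

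The array of +/L mouse 20 had the highest net signal on negative control spots, 41.2 against 21.3 to 25.3 in the other +/L arrays, an intestinal epithelium score of 2.50 against -0.53 to -0.31 and a skeletal muscle score of 1.65 against -0.53 to 0.07. In that tumour Krt8, an epithelial keratin chosen after its value was seen, read 3.90, against -6.35 to -3.42 in the other +/L tumours. The array of +/L mouse 23 had 48.0% of spots well above background, against 60.7% to 64.7% in the other +/L arrays, and Nfkbia at 6.42 against 5.79 to 5.97. In +/L mouse 866, Serpina3c was at -1.23 against -3.27 to -2.76 and Cd79a at -1.52 against 1.13 to 1.55. In +/+ mouse 101, Nosip was at 5.25 against 4.55 to 4.56.

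In +/+ mouse 40, the adipocyte score was 1.78 against -2.05 to -1.01 in the other +/+ tumours, the score of lipid and adipogenic C/EBP targets was 1.04 against -0.96 to -0.62, Retn was at -1.94 against -7.04 to -6.11, and the hepatocyte score was 0.997 against -0.68 to -0.49. In +/+ mouse 11 the immature lymphocyte score was -0.82 against 0.13 to 0.40 and the stress and unfolded protein response score 0.56 against -0.14 to 0.06.

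Xist was at -5.45 in +/+ mouse 101 against 3.08 to 3.49 in the other +/+ tumours, which sets apart the only male-labelled array with Y-linked signal, while the male-labelled arrays of +/L mouse 20 and +/+ mouse 11 have Xist and none of Ddx3y, Eif2s3y and Kdm5d (Uty alone was above background on the former, at -3.33). An exchange of arrays between mice of different sex within the series needs a female-labelled array with Y-linked signal, and 0 of 7 had it. Loss of the Y chromosome in a male tumour needs Xist to be low, and the lower of the 2 arrays read 2.17, above the lowest female-labelled array at 1.83. A wrong sex in the label, or RNA from an animal outside the series, stays open for these 2 mice, was not tested, and bears on their genotype labels as well. No other biological explanation was tested for this pattern.

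At the Serpina cluster of chromosome 12, Serpina1b, Serpina1c and Serpina1d (104968689 to 105137322 in mm9) differed by -2.81, -2.63 and -2.13 in +/L minus +/+ tumours, while Serpina3c and Serpina3m, at 105385352 to 105632400, differed by 3.11 and 2.12, the former well above background on only 1 of 5 +/+ arrays. The pattern did not extend over the cluster. Serpina3f, Serpina3g, Serpina3j and Serpina3n differed by -0.51, -0.32, 0.82 and 0.42 (limma adjusted p = 0.71 to 0.90). Serpina9, Serpina10 and Serpina11 differed by -0.28, 0.09 and 0.61 (limma adjusted p = 0.84 to 0.98). Liver RNA in the +/+ samples is argued against: it would bring Alb, Apoa1 and Ttr, its abundant secreted proteins, and none of these was well above background on any +/+ array, the highest at -5.36, where the 3 Serpina1 genes read 0.58 or more. Signal shared between near-identical Serpina1 transcripts stays open: only 22 to 23 of 60 bases agree between probes, which had been set beforehand to count against it, but that bound was wrong, since the files list the Serpina1c probe for 4 Serpina1 genes and the Serpina1d probe for 3, and the 3 values may be 1 signal. Different haplotypes at several loci in the 2 groups may also account for it; among the 300 genes of lowest p, 39 pairs of unlike name lay within 500000 bases, and 42 of 100 splits of the tumours, the real one included, had as many (highest of the others, 53), which leaves a difference at this locus alone open. An effect of the LIP allele itself stays open and untested.

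Of the 8 named genes with higher values in +/L tumours, 3 (Npr3, Prss55 and Fst) have only a bound, and the other 5 had a median log2 difference of 2.01. With the adipocyte score as a covariate it was 2.26 ± 0.44 (median SE), and with age 1.84 ± 0.52. With the adipocyte score only Aldh1a2 rose, from 2.01 to the median of 2.26. Tph1 fell from 2.66 to 2.46, Serpina3c from 3.11 to 2.61 and Tmie from 1.92 to 1.63, and Ramac fell as well. With age as a covariate Tph1 was at 2.58, Serpina3c at 2.18 and Tmie at 1.34. Neither test excludes fat carried along with the tumours or age, since the genes were picked for their low p between genotypes without passing the threshold, and age goes with genotype. These 2 tests replaced tests on all 8 genes, set before, whose median rested on genes not well above background in +/+ tumours. Fat, age, tumour site, strain background and the genotype all stay open. The size of the differences is likely overstated by this choice of genes.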

How the results depend on the processing

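The adipocyte covariate, limma on list scores and the set without mice 20 and 11 were chosen after seeing the data. The count of 0 genes was 1 on normexp and quantile values and on the deposited value table (ENSMUST00000070897 in both), 0 to 3 when single replicates were left out, 3 at adjusted p under 0.10 and 534 at an unadjusted p under 0.05 with a 2-fold difference. The 3 came without +/L mouse 517 (Tph1, H60a and ENSMUST00000070897); in the other 29 alternatives 0 genes passed. The count of 0 lists was 1 with the slide of the file names as a block (mast cell markers) and 6 with camera's preset correlation. It was 2 when fry tested for change in either direction (inflammatory mediators, and smooth muscle and pericyte genes). Cebpb kept its direction and side of the threshold in all 29 alternatives, from -1.21 to -0.45. The age difference ranged from -8.125 to -5.15 months over leave-outs and lost p under 0.05 without +/+ mouse 40, 11 or 101 (exact permutation p = 0.056). The within-minus-between correlation was 0.080 over the 1000 most variable genes, past the threshold. The log2 variance ratio ranged from 0.21 (without +/L mouse 20) to 1.05 over leave-outs and lost p under 0.05 in 6 of 10 (+/L mice 20, 866, 688 and 517, +/+ mice 40 and 101). The sex fit, on labels of which 2 did not match the arrays, called 0 genes without a filter too. The 16 named genes picked for low p kept their sign in all 453 values. Their groups of 5 values did not overlap, so settings that only leave out mice could not turn a sign. Differences of dim ones were smaller on the deposited value table, with Npr3 at 0.24 and Tph1 at 0.61. The reason was not tested, since the background method behind those values is not given.

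Signs turned in 17 of 1173 values, all of 5 results that did not pass. Cebpd was -0.39 with age, -0.41 with the description's slides, -0.24 among the female-labelled mice, -0.065 without mouse 866, -0.40 with the adipocyte score and -0.065 to 0.44 in leave-outs. The female-labelled set leaves out +/L mouse 20 and +/+ mice 11 and 101, all labelled male. Ddit3 was -0.13 among the female-labelled mice, -0.053 without mice 20 and 11 and -0.053 to 0.25 in leave-outs. Cd79a was 1.14 with age, 0.16 without mice 866 and 17, 0.25 without mouse 866 and -0.51 to 0.25 in leave-outs. Cd8a was -0.031 with age and -0.053 without mice 866 and 17. The lipid target score was -0.20 with the adipocyte score, which shares genes with it, so this setting does not test that result. The cause was not tested, except that leave-outs have fewer samples. The adipocyte list could not be tested with its own score as a covariate.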

Other observations

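The splits for the adjusted p were chosen only after the result was seen; the splits for the unadjusted p were set before.

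Genes that differed widely between tumours did not all follow genotype, and all named here were chosen after their values were seen. H60a, which encodes a ligand of the NK-cell receptor NKG2D, was well above background on all 5 +/+ arrays and on 1 of 5 +/L arrays with one probe, at 0.15 to 1.59 in +/+ tumours, 0.97 in +/L mouse 517 and -6.93 to -3.25 in the other 4 +/L tumours (exact two-sided permutation p = 0.032), which does not tie it to the LIP allele, since strain background was not analysed here. A second H60a probe (chromosome 10, 22026996 to 22027055 in mm9) differed by -0.52 (exact permutation p = 0.26). Prim2, a DNA primase subunit (chromosome 1, 33510733 to 33510792), read -3.41 to -2.63 in +/L mice 866, 688 and 517, and 0.14 to 1.07 in the other 7 tumours. Nkx2-3, a transcription factor of spleen and gut stroma, read -4.73 and -4.14 in +/+ mice 40 and 17 and -1.26 to 0.61 in the other 8. Pancreatic acinar genes had scores of 2.87 in +/+ mouse 19 and 1.55 in +/+ mouse 101, and from -1.36 to 0.82 in the other 8 tumours.

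The main comparison was set against splits of the tumours, the real one included. For the 1525 genes at an unadjusted p under 0.05, 13 of 100 splits drawn gave as many, and the highest of the others gave 2812, so that chance is not excluded for this count. With 0 genes past adjusted p 0.05, all 100 splits had to give as many, which tests nothing; the highest of the others gave 2.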
